A study of Drosophila melanogaster with 3 samples.

How the data were processed

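Chromatin was immunoprecipitated with an antibody against GFP from whole embryos, 0 to 6 h old, of a Drosophila melanogaster line with a zen2-eGFP insertion, per the labels. The antibody field of the labels names zen2, whereas their description names GFP; the tag was taken as the target. Chromatin was sheared by sonication, with a stated fragment size range of 200 to 800 bp, per the labels. The 3 samples were biological replicates 1, 2 and 3 of 1 group, with numbers taken from the labels. The labels name 1 control, which was not used here, nor were the alignments. The aligner, the peak caller and their versions are not given in the sources used here.

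The lists were made from alignments to dm6 of the replicates and the control, per the text files deposited with them, and hold regions matched between 2 inputs and ranked by irreproducible discovery rate (IDR). The authors deposited 7 thresholded lists and the 7 ranked lists behind them: 1 of each per replicate and 4 for the series, of which 1 is called conservative by its name. The other 3 series lists are named here joint lists A, B and C by falling number of peaks. Inspection of the records showed that the inputs of the conservative ranked list matched those of replicates 2 and 3 in 87.3% and 88.8% of records. Neither of its inputs matched replicate 1 in any record (0%). Those of joint list B matched replicates 1 and 3 (61.2% and 91.6%), those of joint list C matched replicates 1 and 2 (61.2% and 90.3%), and those of joint list A matched none (0%). Each deposited score is an IDR on a scaled logarithm, and the authors' −log10 columns hold a q value and, in ranked lists, the local and global IDR. All regions listed as peaks had a global IDR of 0.01 or less. The deposited signal of a peak is the authors' own value, on a scale not given in the sources used here, and was compared only within a list. In the series lists it was taken as the value of the pooled region. How the replicates were normalised to each other is not given, and the lists hold no read counts, so depth per sample is unknown and precision was taken from counts of peaks, genes and windows.

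Gene models came from Ensembl release 115 on assembly BDGP6.54, whose lengths of the 8 chromosomes compared, the mitochondrial genome included, hold every listed region. Coordinates are 1-based. Peaks on the 7 assembled chromosomes (2L, 2R, 3L, 3R, 4, X and Y) were used for positions, genes and motifs. A peak was at a promoter when its summit lay within 500 bp of an annotated start, and a gene carried a peak when a summit lay within 2000 bp of one of its starts. The background of gene lists was all 13968 protein-coding genes on those chromosomes, of which 2782 carried a peak (19.9%). Gene lists were fixed for dorsal ectoderm and amnioserosa, neuroectoderm and ventral midline, mesoderm, gap, terminal and head patterning, pair-rule, segment polarity, Hox genes, BMP signalling, E(spl) and Bearded genes, cellularization, germ cells, endoderm and gut, neuronal differentiation, haemocyte and fat body, photoreceptor and chorion genes, olfactory receptors, ribosomal proteins, heat shock and ubiquitously expressed genes. Of 272 symbols listed by name, 4 were matched through synonyms in the RefSeq gene table (WntD, h, frs and H2Av) and 4 were not matched (lines, BobB, BobC and nos).

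The conservative list was the main peak set, chosen by its name, and "without a replicate" means its peaks overlapped by both other replicate lists. Overlap of replicate lists was counted at 1 bp or more and set against 1000 random placements of the second list within its chromosomes (one-sided). The promoter share was tested the same way, and the distribution over chromosomes by chi-square with 100000 multinomial draws. Gene lists, 27 motifs and all 2080 canonical 6-mers were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family, at a threshold of 0.05. Motif windows reached 100 bp to each side of the summit, and control windows of the same width were centred 1000 bp to each side and overlapped no peak. Log2 odds ratios had 0.5 added to each cell, with 95% intervals by Woolf's formula, and shares have 95% Wilson intervals. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

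Design, gene lists, motifs, tests, the rule for named genes and most other settings were chosen before the data were examined. The rule named genes with a start within 2000 bp of the 15 strongest conservative peaks overlapped by all 3 replicate lists (the nearest gene where there were more than 2), up to 4 members of each list with the strongest peak, peaks in the Antennapedia complex, and up to 6 6-mers per direction. Other members of a called list, and C15, peb, tin and en beside the replicate counts, were named after their values were seen. Some genes that the rule takes are not reported here. The other settings were the other peak lists, each replicate list alone, the upper 50% of conservative peaks by signal, peaks overlapped by all 3 replicate lists or by all but one, other overlap rules, other distances to a start, matched random gene sets or genes near a ranked region as background, other window widths and other control windows. The planned IDR of 0.01 moved nothing, since it is the authors' own threshold. A global IDR of 0.001 and a set without peaks whose summit lay within 1 peak width of a stronger summit were added after seeing the data, as were matched windows for the replicate lists and for peaks overlapped by all 3, 12 gene families, the comparisons of GC content and promoter share between replicates and the gap at zen2. Of these, the GC comparisons of the strongest and weakest regions had their expected outcomes set before they were computed.

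The procedures were tested on simulated data. Of 5 motifs and 20 6-mers planted in 10% of windows, 5 and 20 were recovered, with 0 calls among 27 motifs and 1 among 2080 6-mers where nothing was planted. Of 19 gene lists with 60% of members added as hits, 15 were recovered, with 0 calls where none was added. A list with 30% of its peaks copied from another gave an overlap of 33.7%, and an unrelated list gave a permutation p of 0.249.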

Results

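Genomic sites of the homeodomain protein Zen2 were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos aged 0 to 6 h. The gene zen2 lies in the Antennapedia complex beside its paralog zen, which specifies the amnioserosa, an extraembryonic tissue of the dorsal side. The embryos carried zen2 fused to eGFP, and chromatin was precipitated through the GFP tag. The design held 3 biological replicates of 1 group and no second condition, so the comparisons asked which genes and sequences lay under the peaks and how far the replicates shared them. The replicate lists held 2414, 1720 and 1794 peaks (1976 ± 381, SD, n = 3), selected from 39780, 142700 and 150885 ranked regions. No interval was identical between any pair of replicate lists, but their median widths differed (396, 330 and 370 bp), so this says little about their independence. The main peak set was the deposited conservative joint list, with 2401 peaks, of which 2376 lay on the 7 assembled chromosomes of dm6. The records of its inputs were identical to those of replicates 2 and 3 in 87.3% and 88.8% of cases and to those of replicate 1 in 0%. Overlap with replicate 1 is therefore overlap with records not found among its inputs. The text files deposited with the lists name all 3 replicates as inputs, however, so this overlap is not an independent check. Leaving out replicate 1, 2 or 3 keeps only the peaks overlapped by both other lists, 1147, 1038 and 1049 of the 2376. Each of these sets holds the 892 peaks overlapped by all 3 replicate lists, so they are not separate checks. With fewer peaks a call can be lost without a change in odds ratio. The deposited lists give no read counts, so the depth of each library is unknown. A peak's signal is the authors' own value, was used only to rank peaks within that list, and has no replicate error.

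Peaks stood mostly at the starts of genes. The strongest peak (2L, 102195 to 102513, signal 1148) lay 20 bp from the start of Creld and carried a DREF site, TATCGATA, within 100 bp of its summit. The next (2R, 14752210 to 14752568, signal 1144) lay 94 bp from a start of Rpn6, which encodes a subunit of the proteasome lid, and 156 bp from that of ave, which encodes an adaptor of the EGF receptor pathway. It was followed by the promoter of mtSSB, which binds single-stranded mitochondrial DNA (3R, 16205145 to 16205457, signal 1132), 1918 bp from the start of CG31287. Other genes at the 15 strongest peaks shared by all 3 replicates included RpL32, a ribosomal protein gene, and its divergent neighbour CG7943 (signal 948). They also included Ube3a, a ubiquitin ligase, with CG7600 (933), and Pym, a partner of the exon junction complex, within bgcn (976). Further genes were MESK2 with TAF1C-like (913), the adducin gene hts with the calpain gene CalpA (907), CG30015 (870), the TSC22-family gene bun (851), the kindlin gene Fit2 (851), CG4502 (845), and the cathepsin gene CtsF with CG1113 (815). The fourth strongest peak (X, 8452211 to 8452535, signal 996) was the exception, lying in an intron of the T-box gene org-1, 2504 bp from the nearest start.

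The summit lay within 500 bp of an annotated start for 1909 of 2376 peaks, 80.3% (95% Wilson interval 78.7 to 81.9). Random placement within chromosomes gave 16.7% on average and 18.9% at most over 1000 placements (one-sided permutation p = 0.001, the smallest that 1000 placements can give). In the replicate lists the share was 88.8% ± 4.76 (SD, n = 3), above the random level in 3 of 3 replicates. A further 278 summits lay more than 500 and up to 2000 bp from a start and 189 (7.95%) lay farther away, 107 of these in introns. The promoter share was 97.1% in the strongest decile of the peaks and 47.1% in the second decile from the bottom. The lowest decile, at 62.6%, held 144 of the 155 peaks whose summit lay within 1 peak width of a stronger peak. Intervals here and below cover counting error only.

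**Figure D1:**
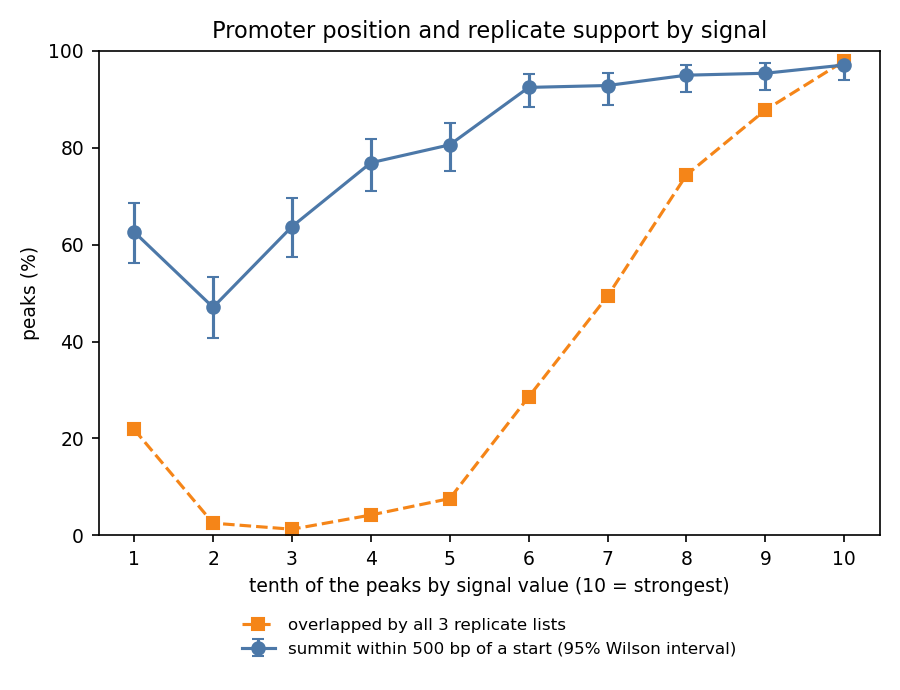
Share of conservative-list peaks on the assembled chromosomes (%, vertical axis) with the summit within 500 bp of a transcription start (circles, bars are 95% Wilson intervals) and overlapped by the lists of all 3 replicates (squares), by decile of the authors' signal (horizontal axis, 10 is the strongest). In the strongest decile the shares were 97.1% and 97.9%, and in the second decile 47.1% and 2.52%.

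In the conservative list, genes of the dorsal ectoderm and amnioserosa list carried peaks more often than other genes. Of 20 dorsal ectoderm and amnioserosa genes, 10 had a summit within 2000 bp of a start, against 19.9% of other protein-coding genes (50%, Wilson interval 29.9 to 70.1, adjusted exact p = 0.0158). They included ush, which encodes a cofactor of GATA factors (2L, 490632 to 490840, in the 5′ UTR of ush, signal 497), C15, a homeobox gene (3R, 21499441 to 21499856, signal 244), and peb, a zinc finger gene needed for germ band retraction (X, 4617292 to 4617707, signal 205). Ance, a peptidase gene of the dorsal midline, was also among them (signal 203), but this summit lay 1107 bp from its start, in the 5′ UTR of Smg5. The other members with a peak were cv-2, pnr, srp, tup, Doc1 and Doc2. Members without one included zen, zen2, dpp, scw, tld and tsg, of which dpp, scw, tld and tsg are also on the BMP signalling list. Among 18 genes of BMP signalling, the pathway that patterns the dorsal side, 9 carried a peak (50%, adjusted exact p = 0.0195), among them the receptor genes wit (signal 320) and tkv (247), the ubiquitin ligase gene Smurf (320) and the ligand gene gbb (273). Of 11 pair-rule genes, which set the segment pattern, 6 had a peak (54.5%, adjusted exact p = 0.0433), with sob (280), ftz-f1 (251), odd (226) and slp2 (149) the strongest. These 3 calls were lost against random gene sets matched on number of starts and gene length and with any 1 replicate left out: without replicates 1, 2 and 3 the dorsal ectoderm share was 30.0%, 10% and 5%, the BMP share 38.9%, 16.7% and 16.7%, and the pair-rule share 27.3%, 9.09% and 9.09%, against 11.5%, 11.7% and 11.6% of other genes. In the replicate 1 list 10% of the dorsal ectoderm, 18.2% of the pair-rule and 27.8% of the BMP genes had a peak, against 25.5% of other genes, and none of these differences passed the threshold. Of 85 ribosomal protein genes, 29 carried a peak (34.1%, Wilson interval 24.9 to 44.7, against 19.8%, adjusted exact p = 0.0158), with RpL32 (948), RpLP1 (687), RpS2 (606) and RpS27 (599.5) leading. The summits for RpLP1 and RpS27 lay 1549 and 1785 bp from their starts. Here and in the lists below, a counted summit could lie nearer to another gene.

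Olfactory receptor genes, a control list, were the only list called below other genes, with 2 of 59 carrying a peak (3.39%, adjusted exact p = 0.00844), Or9a (signal 268) and Or88a (127). The remaining 14 lists did not pass. Of 13 segment polarity genes, 6 had a peak (46.2%, adjusted exact p = 0.0931), led by the Hedgehog receptor gene ptc (252), Wnt4 (189), en (160.4) and wls (126). The wls summit lay in the 5′ UTR of Adck5. Of 8 Hox genes, 3 had one (adjusted exact p = 0.382), all in the Bithorax complex: Ubx (236), abd-A (183) and Abd-B (138). Gap, terminal and head patterning had 6 of 18 (adjusted exact p = 0.315), led by pdm2 (306), croc (154), slp2 and Optix (143). Neuroectoderm and ventral midline also had 6 of 18 (adjusted exact p = 0.315), with D (199), vn (156) and pyr (147) among them. Mesoderm had 5 of 18 (adjusted exact p = 0.517), with Mef2, a regulator of muscle genes (307), zfh1 (170.3), tin (105) and how (104). Endoderm and gut had 4 of 12 (adjusted exact p = 0.432), with srp (197), fkh (137), bowl (135) and pnt (126). Germ cell genes had 4 of 13 (adjusted exact p = 0.447), with bgcn (976), piwi (491), tud (314) and gcl (122). The bgcn summit lay 1966 bp from a bgcn start but 19 bp from that of Pym, and the piwi summit 1945 bp from its start.

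The lists of other cell types had few members with a peak, but none differed from other genes past the threshold. Of 16 neuronal differentiation genes only Rab3 did (signal 98.3, adjusted exact p = 0.384), of 26 photoreceptor and chorion genes only norpA (321, adjusted exact p = 0.124), and of 15 haemocyte and fat body genes only ush and crq (129, adjusted exact p = 0.791). The cellularization list had a peak at 1 of 13 genes, Sry-alpha (615, adjusted exact p = 0.615), and the E(spl) and Bearded list at 2 of 15, E(spl)m3-HLH (122) and E(spl)m7-HLH (88.7, adjusted exact p = 0.791). Heat shock genes had 4 of 16 (adjusted exact p = 0.642), with Hsp68 (747), DnaJ-1 (519), Hsp83 (155) and Hsp22 (109), and ubiquitously expressed genes 3 of 18 (adjusted exact p = 1), His2Av (242), His3.3A (146) and alphaTub84B (124).

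These were two-sided Fisher's exact tests over 19 lists with Benjamini-Hochberg adjustment. Against 10000 such matched random gene sets, only the ribosomal protein list stayed past the threshold, and the matched sets had a peak at 25.1% of genes for the dorsal ectoderm list. In the list of replicate 2, 40.0% of the dorsal ectoderm and 36.4% of the pair-rule genes had one, against 15.8% of other genes, and in that of replicate 3, 35.0% and 36.4% against 16.5%. Ribosomal protein genes stood above other genes in all 3 replicate lists, with 54.1% against 25.3%, 27.1% against 15.7% and 35.3% against 16.4%. The olfactory receptor share was 1.69%, 3.39% and 1.69% without replicates 1, 2 and 3, against 11.6%, 11.7% and 11.6% of other genes, and did not pass the threshold. The ribosomal protein share was 21.2% against 11.5% of other genes without replicate 1, 22.4% against 12.9% with nearest starts only and 35.3% against 25.1% with gene bodies extended by 2000 bp. All 3 fell short of the threshold, with log2 odds ratios of 1.08, 0.99 and 0.71 beside 1.08 in the conservative list.

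**Figure D2:**
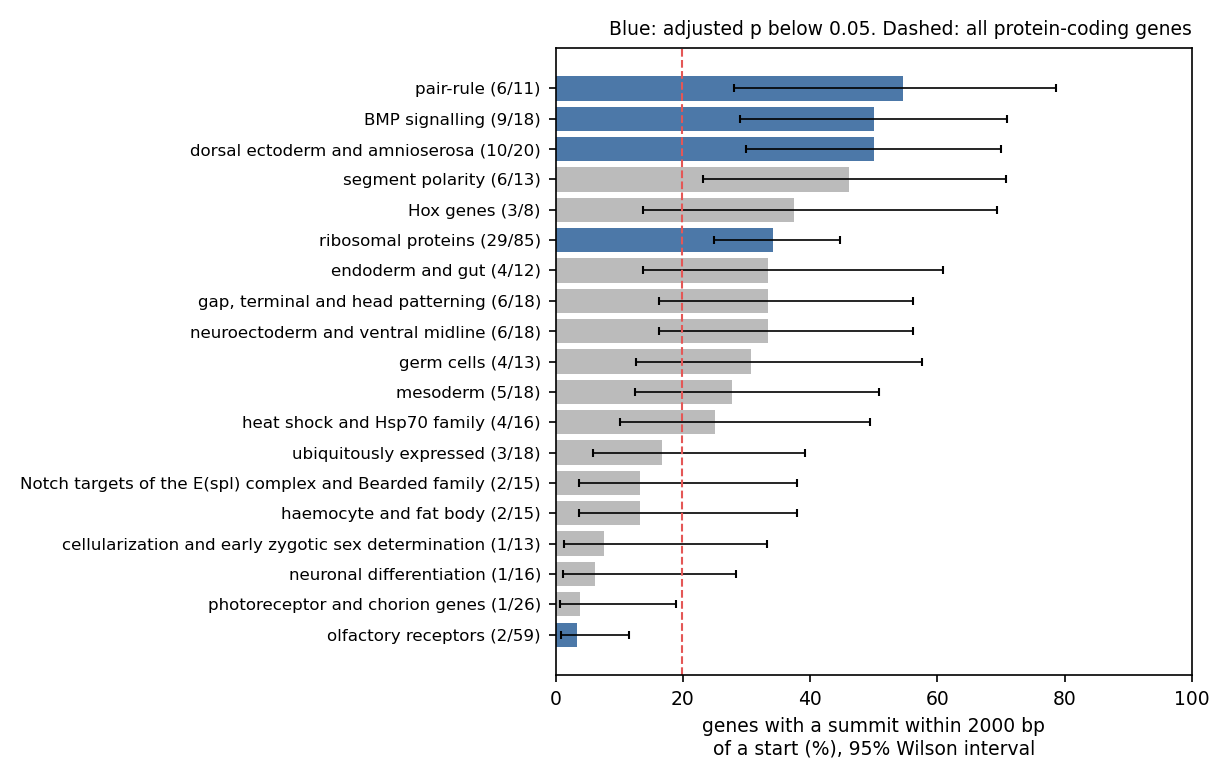
Share of the protein-coding genes of each fixed list (%, horizontal axis) with a conservative-list summit within 2000 bp of a transcription start, with 95% Wilson intervals, genes with a peak and genes in the list beside each name. The dashed line marks all protein-coding genes (19.9%); blue bars passed an adjusted exact p of 0.05.

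No peak of any of the 7 lists lay in zen2 or zen themselves. The gene zen2 occupies 3R from 6743135 to 6744136 on the minus strand, between pb, a Hox gene, and zen (6752864 to 6754194). The nearest conservative peak lay in an intron of pb (3R, 6735694 to 6736109, signal 106), 7233 bp from zen2. Replicates 2 and 3 had closer peaks that the conservative list did not hold: overlapping peaks in the 5′ UTR of pb (6741470 to 6741799 in replicate 2 and 6741388 to 6741757 in replicate 3) and, in replicate 2, another (6742078 to 6742407) 892 bp from zen2. Replicate 1 had no peak within 15 kb of zen2. Across the Antennapedia complex, from lab to Antp (6661427 to 6999228), the conservative list held 3 peaks. Apart from the peak near zen2, these lay in a second intronic site of pb (6708849 to 6709264, signal 153) and at 6816157 to 6816572 (signal 119), between Dfd and Scr.

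The ranked regions, which include those below the threshold, left zen2 itself in a gap of 12254 bp in the conservative list and in joint list A (6738038 to 6750291). In those same 12254 bp, replicates 2 and 3 had 14 ranked regions each and replicate 1 had 0. A gap of at least that length covered 13.8% of the positions of the 5 chromosome arms in the conservative ranked list and held the start of 15.1% of protein-coding genes. The labels describe a transgenic line with a zen2-eGFP insertion, and whether it carried extra copies of this locus is not given in the sources used here.

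**Figure D3:**
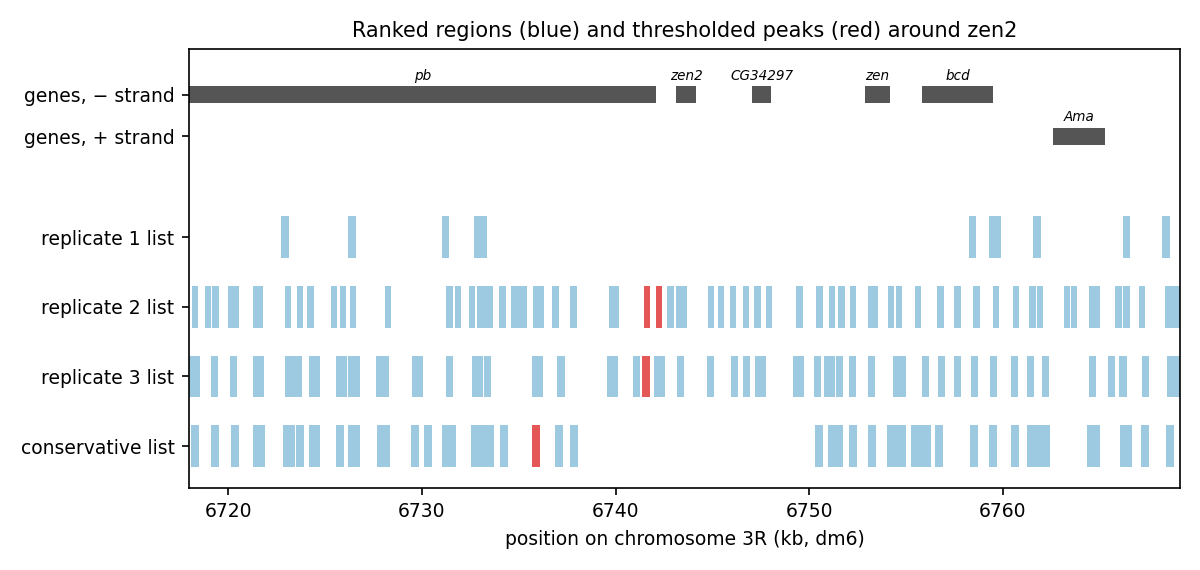
Ranked regions (blue) and thresholded peaks (red) of the replicate and conservative lists along chromosome 3R (horizontal axis, kb, dm6), with protein-coding genes by strand above. Replicates 2 and 3 had regions between pb and zen where the conservative list had none from 6738038 to 6750291.

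Sites of promoter and boundary factors lay under the peaks, and homeodomain sites did not stand out. The DREF site TATCGATA, bound by a regulator of replication and growth genes, was within 100 bp of 20% of 2376 summits and in 0.461% of 4554 windows 1000 bp away (log2 odds ratio 5.72, 95% interval 5.09 to 6.35, adjusted exact p = 1.82e-201). The motif 1 site of M1BP, GGTCACACT, was in 3.83% against 0.154% (4.6), the BEAF-32 boundary site CGATAW in 43.1% against 15.6% (2.03), and the GAGA factor site GAGAGA in 19.9% against 7.05% (1.72). The GAGAGA ratio was 0.39 in the replicate 1 list and 0.66 in peaks overlapped by all 3 replicate lists, and against windows matched on GC content and distance to a start it fell to 0.26 and 0.33 there and did not pass. In windows without a DREF site, CGATAW was still more frequent, in 32.0% against 15.3% (log2 odds ratio 1.38, Fisher's exact p = 2.32e-49). Grainyhead (2.06), CACGTG (0.83), GATA (0.66), the CACACACA repeat (0.50) and the Mad and Brinker site GGCGCC (0.47) were also higher, with adjusted exact p from 5.61e-08 for GATA to 0.00940 for GGCGCC. Grainyhead, GGCGCC and the CACACACA repeat lost their calls with any 1 replicate left out: without replicates 1, 2 and 3 the ratios were 1.71, 0.99 and 1.64 for Grainyhead, 0.47, 0.14 and 0.30 for GGCGCC, and 0.013, −0.25 and −0.45 for CACACACA. The DREF site lay under 37.2% of the strongest decile of the peaks and 5.02% of the lowest.

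The homeodomain site TAATTA was in 8% of the peak windows and 9.88% of the control windows (log2 odds ratio −0.33, 95% interval −0.59 to −0.08, adjusted exact p = 0.0167). YAATTA (−0.22), TAATKG (−0.23), the Bicoid class site TAATCC (−0.89) and the Caudal and Abd-B class site TTTATG (−0.50) were lower too. The same held for Tramtrack (−1.56), Snail (−0.67), Twist (−0.62) and Su(H) (−0.32), with adjusted exact p from 2.04e-47 for Tramtrack to 0.0254 for YAATTA. Zelda sites, marks of early zygotic enhancers, did not pass for CAGGTAG (−0.68, adjusted exact p = 0.0710) or CAGGTA (−0.13, adjusted exact p = 0.509). The other motifs that did not pass were Dorsal, TATA box, Stat92E, Pho, Hunchback poly-T, Kruppel and Odd-paired, with log2 odds ratios from −0.35 to 0.21. Of 27 motifs, 9 were higher and 9 lower (two-sided Fisher's exact tests with Benjamini-Hochberg adjustment). Against windows 1000 bp away the sign for TAATTA depended on the peak set: it was 0.70 in the replicate 1 list, 0.55 in peaks overlapped by all 3 replicate lists, and −0.020, 0.60 and 0.44 without replicates 1, 2 and 3. It passed as higher in all of these but the set without replicate 1, and so did YAATTA, at 0.75 in the replicate 1 list and 0.50 in peaks overlapped by all 3. Under the same 3 settings YAATTA was at 0.028, 0.61 and 0.50, TAATKG at −0.14, 0.28 and 0.21, and TTTATG at −0.43, 0.0037 and −0.036, and Su(H), at −0.35, −0.38 and −0.35, did not pass. CAGGTA passed without replicates 2 (−0.61) and 3 (−0.67), poly-T passed there too (0.79 and 0.66), and so did the TATA box (0.45 and 0.38). Against windows matched on GC content and distance to a start TAATTA was below 0 in each of the 5 peak sets run. It did not pass in the conservative list (−0.18), in peaks overlapped by all 3 replicate lists (−0.17), in the replicate 1 list (−0.042, 13.4% against 13.8%) or in the replicate 2 list (−0.30), and passed as lower in the replicate 3 list (−0.32). Against such windows YAATTA and TAATKG also passed as lower in the lists of replicate 2 (−0.35 and −0.44) and replicate 3 (−0.31 and −0.29). Mean GC content at the summits was 39.5% in replicate 1, 44.5% in replicate 2 and 43.6% in replicate 3, against 46.0%, 44.7% and 44.9% in the windows 1000 bp away. It was 40.9% against 46.1% for peaks overlapped by all 3 replicate lists, and 44.8% against 44.7% for the conservative list.

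**Figure D4:**
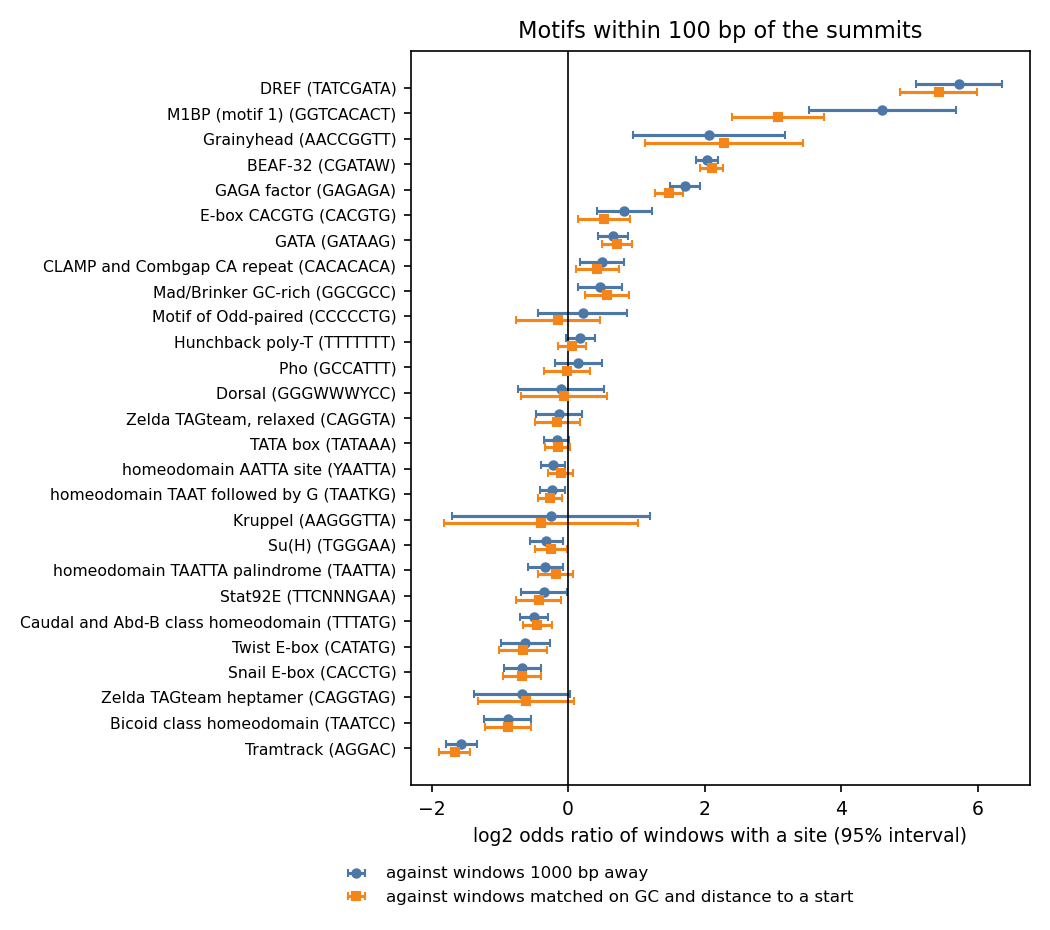
Log2 odds ratio (horizontal axis, 95% intervals) of a site within 100 bp of a conservative-list summit for 27 motifs, against windows 1000 bp away (circles) and against windows without a peak matched on GC content and distance to a start (squares). DREF lies at 5.72 and 5.43, and Tramtrack at −1.56 and −1.66.

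Among all 2080 canonical 6-mers, the 6 with the smallest p among those more frequent under the peaks were led by pieces of the DREF site, and 5 of them contained ATCG or the reverse complement CGAT, both parts of that site. TATCGA, CGATAG, ATATCG and CGATAA also hold CGATA, shared with the BEAF-32 site CGATAW, or its reverse complement. The 6-mers therefore do not tell the DREF and BEAF-32 sites apart. TATCGA was in 43.6% of peak windows and 7.20% of controls (log2 odds ratio 3.31), ATCGAT in 39.4% and 5.97%, CGATAG in 36.2% and 4.72%, ATATCG in 26.0% and 7.18%, ACTATC in 21.6% and 4.94%, and CGATAA in 27.9% and 8.98%. The 6 leading those less frequent were CCAGGA, in 3.16% and 10.8% (−1.89), CAAGGA, CCTCCA, AAGGAT, AGGATG and GCAGGA, with log2 odds ratios from −1.89 to −1.43. In all, 400 were higher and 612 lower (adjusted exact p from 7.65e-273 for TATCGA and 2.27e-30 for CCAGGA).

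The replicate lists overlapped most of the conservative peaks with the highest signal. Of the replicate 1 peaks, 45.8% overlapped a replicate 2 peak (Wilson interval 43.8 to 47.8) and 50.3% a replicate 3 peak. Of the replicate 2 peaks, 60.7% overlapped replicate 1 and 65.1% replicate 3, and of the replicate 3 peaks, 66.2% overlapped replicate 1 and 64.2% replicate 2. Random placement of the second list gave at most 2.29% (1000 placements, one-sided permutation p = 0.001 for each of the 6 comparisons, the smallest possible). All 3 replicate lists overlapped 892 conservative peaks, 37.2% (35.2 to 39.1), and none overlapped 467, 19.5%. The peaks at Creld, Rpn6, mtSSB and RpL32 were in all 3 lists, those at C15 and peb in 2 and those at tin and en in 1. Overlap by all 3 was 21.6% in the lowest signal decile, 2.5% in the second and 97.5% in the strongest. The signal of this list was taken as that of the region in pooled data. A rise of overlap with signal is therefore in part built in.

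**Figure D5:**
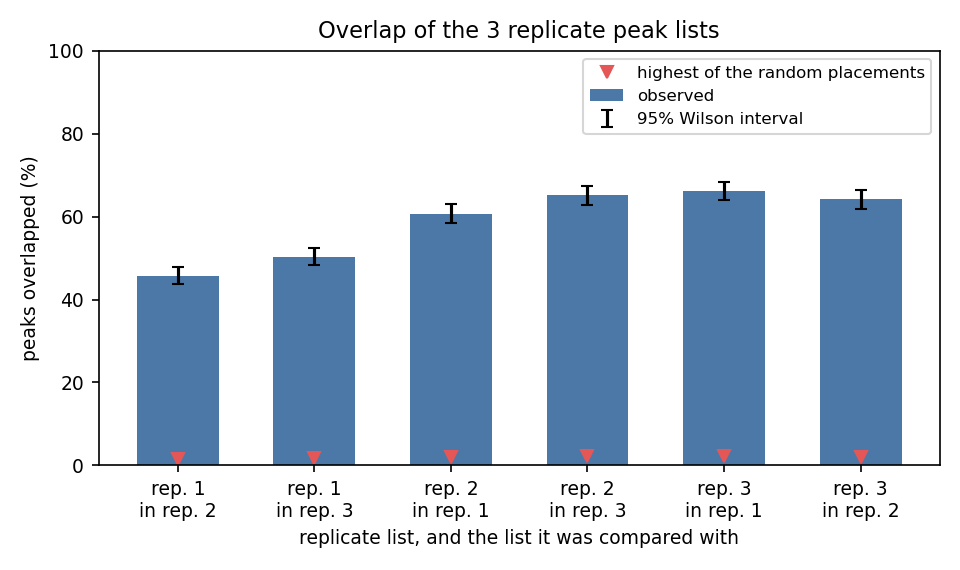
Share of the peaks of each replicate list (%, vertical axis, 95% Wilson intervals) that overlapped a peak of another replicate list by 1 bp or more (horizontal axis, each pair in both directions). Observed shares ran from 45.8% to 66.2%, and the highest of 1000 random placements (triangles) was at most 2.29%.

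Across regions, which are not independent replicates, the signals of the 2 inputs matched in each ranked list had Spearman correlations of 0.179 to 0.331 over all regions. Among regions past the threshold, which were selected for a low IDR between those inputs, the correlations were 0.355 to 0.758. In the upper part by summed signal, 6 of the 7 lists turned negative, down to −0.241 in replicate 3. Selection on a sum of 2 values lowers their correlation by construction, so neither value measures how well the inputs matched.

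Chromosome 2R had the most peaks per Mb, 21.8 (552 peaks), and X the fewest of the large arms, 15.2 (359 peaks). Chromosome 3R held more peaks, 576, at 18.0 per Mb. The 4 peaks on chromosome 4, which is largely heterochromatic, compared with 23.3 expected from its length, and the heterochromatic Y had 0 against 63.3. Expected counts used full assembled lengths, without allowance for sequence where reads cannot be placed. Low counts there therefore do not show absence of binding. The distribution differed from chromosome lengths (chi-square 117, permutation p = 1e-05 from 100000 multinomial draws, the smallest possible), and also over the 5 arms 2L, 2R, 3L, 3R and X alone (33.6, p = 1e-05, the smallest possible). The place of X was not shared by the replicates: replicate 1 had 20.3 peaks per Mb on X and 19.6 on 2R, replicate 2 had 11.0 and 16.2, and replicate 3 had 11.8 and 17.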

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

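The tests of homeodomain sites, of the gap at zen2, of ubiquitously expressed genes, of GC content at matched ranks and of the promoter share of the 500 strongest peaks were chosen after the results were seen. Peaks outside the assembled chromosomes and regions left out of the thresholded list entered no comparison, and their numbers are given first.

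The replicate 1 list held 4 peaks on the mitochondrial genome, the strongest at mt:CoII (3287 to 3848, signal 4533) and 3 in mt:CoI, and the other 6 lists held 0. The conservative list held 25 peaks on unplaced scaffolds, all assigned to X, with signals up to 378. The conservative ranked list held 128 regions past the IDR threshold that the thresholded list left out, 107 of them on assembled chromosomes, with a median signal of 156 against 167 for listed peaks.

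DREF sites were frequent under the peaks. Position at promoters alone would bring the log2 odds ratio of TATCGATA to 0 against windows matched on GC content and distance to a start. It was 5.43 (4.87 to 5.99). These windows held no peak, so sites under peaks could not occur in them. Whether they lay as close to starts as the summits, at a median of 71 bp, was not tested. The windows therefore cannot exclude promoter position. In a contrast of genes chosen after the results were seen, 48% with a DREF site near a start carried a peak. Without a site it was 15.7% (log2 odds ratio 2.31, 2.16 to 2.46), so peaks at starts went with the site. This contrast used the same peaks, and genes were not matched on number of starts. Direct recognition of TAATTA in most peaks would put the log2 odds ratio of that site above 0 against the matched windows. It was −0.18 (−0.44 to 0.08), and −0.042 (−0.25 to 0.16) in the replicate 1 list, where it was 0.70 against windows 1000 bp away. Capture of the most transcribed promoters irrespective of sequence stays open as a candidate explanation. Among genes without a DREF site near a start, ribosomal protein genes carried a peak more often than others (25.9% against 15.7%, log2 odds ratio 0.94, 95% interval 0.10 to 1.78, Fisher's exact p = 0.0446). Only genes with TATCGATA were taken out, so other sites, such as CGATAW, could still lie at these promoters. Transcription was not measured, so the contrast cannot separate transcription from sequence. Ubiquitously expressed genes give capture of transcribed promoters no clear support, with a peak at 20% of the 15 without a DREF site (log2 odds ratio 0.59, −1.12 to 2.30) and at 16.7% of all 18 against 19.9% of other genes. Among other families of housekeeping genes, with or without a DREF site, the share ran from 17.5% for complex I subunits to 50% for chaperonin subunits. Of these only mitochondrial ribosomal protein genes, at 31.5%, passed the threshold. The design has no untagged or second protein to set against these peaks, and no biological explanation beyond recognition of homeodomain sites was tested.

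The replicate 1 list was richer in A and T and in promoters than those of replicates 2 and 3. If it were a shallower library that kept only the strongest sites, the 500 strongest peaks of each replicate would have like GC content, and replicate 1 was 3.52 percentage points below the lower of the others (37.2% against 42.1% and 40.7%, standard errors 0.265, 0.315 and 0.318). For the promoter share this explanation stays open. Replicate 1 exceeded the higher of the others by 7.15 percentage points over the whole lists. Among the 500 strongest peaks it did so by 2.8 (95% interval 0.436 to 5.16), where shares of 97.6%, 94.2% and 94.8% left little room to differ. The lengths of its lists go both ways. Replicate 1 had the most peaks, 2414 against 1720 and 1794, but the fewest ranked regions, 39780 against 142700 and 150885. A base composition bias throughout the library stays open too, because its test decided nothing: the 2000 weakest ranked regions of replicate 1 were higher in GC content (45.9% against 44.2% and 43.3%, a difference of −2.53 percentage points), but its ranked list is shorter, and at the same ranks, 37646 to 39645, the last of replicate 1 only, its content was 45.9% against 47.4% and 46.4%, 0.474 points below the lower of the others with a standard error of 0.259. No biological explanation was tested, since the replicates are of 1 group.

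No region of the conservative ranked list lay in the 12254 bp around zen2. Sequence that cannot be aligned would leave the replicates empty too, but 14 ranked regions lay there in each of replicates 2 and 3. A chance gap stays open: gaps as long covered 13.8% of the positions of the arms, and 3 of the 784 held as many regions of both replicates, that at zen2 and 2 longer ones (25239 and 22185 bp). Per kb, 1 of them, or 0.128%, held as many (1.14, the next highest 1.02), and 4, or 0.510%, held a peak of both replicates, the gap at zen2 being among them each time; both counts go against chance, but its regions and peaks had been seen before the counts were chosen. What the authors' matching of inputs or filters did in this interval is not given in the sources used here and stays open, as do extra copies of the locus in the transgenic line, which were not tested, and no biological explanation was tested.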

How the results depend on the processing

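The IDR of 0.001, the set without peaks beside a stronger peak and matched windows for peak sets other than the conservative list were chosen after seeing the data, and the other settings were planned. No paired analysis was possible because the series has 1 group. The planned IDR of 0.01 equals the authors' threshold and moved nothing. For the changes below the cause was not tested, except that a stricter IDR leaves fewer peaks, selection on summed signal lowers and selection on IDR raises the correlation of the inputs by construction, and depth could not be weighed because the lists hold no read counts. For TAATTA, windows matched on GC content and distance to a start took the ratio from 0.70 to −0.042 in the replicate 1 list. Among peaks overlapped by all 3 replicate lists it went from 0.55 to −0.17. The higher TAATTA ratios of these sets were thus not kept once both were matched, and GC content and distance were not matched separately. Replicate overlap kept its direction and call under 24 of 24 alternatives, the promoter share under 16 of 16, the chromosome distribution under 14 of 14, and the 6-mer counts stayed within 1.5 times the reported ones under 34 of 34. The calls for M1BP, BEAF-32, Snail, TAATCC and Tramtrack were kept under all 18 alternatives run for them, that for DREF under 22 of 22 and that for GAGA factor under 20 of 22, with log2 odds ratios from 0.26 to 1.83. Of 361 gene list results, 309 were the same, 46 lost and 2 gained a call and 4 reversed, and of 506 motif results, 374 were the same, 65 lost and 26 gained a call and 41 reversed.

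At an IDR of 0.001 the peak counts were 1513, 792 and 886 for replicates 1 to 3, 882 for the conservative list and 1324, 1130 and 905 for joint lists A, B and C. Support by all 3 replicates was 19.5% with a reciprocal overlap of 50%, 33.3% with summits within 100 bp, 67.0% in the upper 50% by signal, and 43.2% to 48.1% with 1 replicate left out. In the upper part by summed signal the Spearman correlation of the inputs was 0.102 in replicate 1 and reversed to −0.227 in replicate 2, −0.241 in replicate 3, −0.126 in the conservative list and −0.0624, −0.0134 and −0.0309 in joint lists A, B and C. Past the threshold it was 0.746, 0.570, 0.589, 0.661, 0.758, 0.473 and 0.355 in the same order.

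For shares of genes with a peak, the following changed, none of the reversed ones past the threshold. The share of other genes moved with the number of peaks and was 11.5% to 11.7% for the dorsal ectoderm list with 1 replicate left out. With joint list A, dorsal ectoderm at 50% and pair-rule genes at 63.6% fell short of the threshold. With joint list B, dorsal ectoderm at 25.0%, pair-rule genes at 18.2% and BMP signalling at 44.4% fell short of the threshold. With joint list C, dorsal ectoderm at 30.0%, pair-rule genes at 18.2% and BMP signalling at 38.9% fell short of the threshold. In the replicate 1 list, dorsal ectoderm at 10% and pair-rule genes at 18.2% reversed. BMP signalling at 27.8% fell short of the threshold. In the replicate 2 list, pair-rule genes at 36.4% fell short of the threshold. Segment polarity at 46.2% passed it. In the replicate 3 list, dorsal ectoderm at 35.0%, pair-rule genes at 36.4% and BMP signalling at 38.9% fell short of the threshold. In the upper 50% of the peaks by signal, dorsal ectoderm at 25.0%, pair-rule genes at 27.3% and BMP signalling at 22.2% fell short of the threshold. Among peaks overlapped by all 3 replicate lists, dorsal ectoderm at 5% reversed. Pair-rule genes at 9.09%, BMP signalling at 16.7% and olfactory receptors at 1.69% fell short of the threshold. At an IDR of 0.001, dorsal ectoderm at 25.0%, pair-rule genes at 27.3% and olfactory receptors at 1.69% fell short of the threshold. Within 500 bp of a start, pair-rule genes at 45.5% fell short of the threshold. Within 5000 bp of a start, dorsal ectoderm at 55.0% and pair-rule genes at 54.5% fell short of the threshold. Photoreceptor and chorion genes at 7.69% passed it. With gene bodies extended by 2000 bp, pair-rule genes at 54.5% and ribosomal proteins at 35.3% fell short of the threshold. With the nearest start only, ribosomal proteins at 22.4% fell short of the threshold. Against the 11930 genes near a ranked region, pair-rule genes at 54.5% and BMP signalling at 50% fell short of the threshold. Against matched random gene sets, dorsal ectoderm at 50%, pair-rule genes at 54.5%, BMP signalling at 50% and olfactory receptors at 3.39% fell short of the threshold. With 1 replicate left out, the shares were 5% to 30.0% for dorsal ectoderm, 9.09% to 27.3% for pair-rule genes and 16.7% to 38.9% for BMP signalling. They were 1.69% to 3.39% for olfactory receptors and 21.2% to 28.2% for ribosomal proteins. Lists called higher, 4 with the conservative list, were 2 with joint list A, at an IDR of 0.001, within 5000 bp, with gene bodies and against genes near a ranked region. They were 1 with joint lists B and C, in the lists of replicates 1 and 3, in the upper 50%, with all 3 replicates and against matched sets, and 0 to 1 with 1 replicate left out. Lists called lower, 1 with the conservative list, were 2 within 5000 bp and 0 with all 3 replicates, with any 1 replicate left out, at an IDR of 0.001 and against matched sets.

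For log2 odds ratios of motifs, the following changed. Of the 41 reversed results, 20 passed the threshold in the opposite direction. These were TAATTA and YAATTA in the replicate 1 list, among peaks overlapped by all 3 replicate lists and without replicates 2 and 3, YAATTA also with joint list B, in the upper 50% by signal and in windows of 250 bp, and TAATKG and the CA repeat in the replicate 1 list. The others were the TATA box with joint lists B and C, in the replicate 1 list, in windows of 250 bp and without replicates 2 and 3, and Pho against low-ranked regions. With joint list A, Mad/Brinker at 0.21 fell short of the threshold. Stat92E at −0.39 and poly-T at 0.32 passed it. With joint list B, TAATTA at 0.26, YAATTA at 0.39, TAATKG at 0.079 and the TATA box at 0.31 reversed. TTTATG at −0.21, the CA repeat at 0.16, Mad/Brinker at 0.12 and Grainyhead at 0.85 fell short of the threshold. Poly-T at 0.77 passed it. With joint list C, TAATTA at 0.077, YAATTA at 0.17 and the TATA box at 0.26 reversed. TAATKG at −0.027, TTTATG at −0.13, the CA repeat at 0.12, Mad/Brinker at 0.33, Su(H) at −0.26 and Grainyhead at 1.52 fell short of the threshold. Poly-T at 0.74 passed it. In the replicate 1 list, TAATTA at 0.70, YAATTA at 0.75, TAATKG at 0.32, TTTATG at 0.18, the CA repeat at −0.55, Mad/Brinker at −0.055 and the TATA box at 0.80 reversed. Twist at −0.35 and Su(H) at −0.18 fell short of the threshold. CAGGTA at −0.47 and poly-T at 1.11 passed it. In the replicate 2 list, the CA repeat at 0.42 and Su(H) at −0.24 fell short of the threshold. Stat92E at −0.45 passed it. In the replicate 3 list, TAATTA at −0.24, YAATTA at −0.11, TAATKG at −0.14 and the CA repeat at 0.15 fell short of the threshold. Stat92E at −0.48 and poly-T at 0.31 passed it. In the upper 50% of the peaks by signal, TAATTA at 0.33, YAATTA at 0.32, TAATKG at 0.0081 and the CA repeat at −0.31 reversed. TTTATG at −0.16, Mad/Brinker at 0.20, Su(H) at −0.37 and Grainyhead at 1.72 fell short of the threshold. CAGGTAG at −1.16, CAGGTA at −0.58 and poly-T at 0.86 passed it. Among peaks overlapped by all 3 replicate lists, TAATTA at 0.55, YAATTA at 0.50, TAATKG at 0.17 and the CA repeat at −0.46 reversed. TTTATG at −0.032, Mad/Brinker at 0.34, Su(H) at −0.38 and Grainyhead at 1.35 fell short of the threshold. Poly-T at 0.58 passed it. At an IDR of 0.001, TAATTA at 0.16, YAATTA at 0.15 and the CA repeat at −0.0027 reversed. TAATKG at −0.021, Twist at −0.53, Mad/Brinker at 0.32, Su(H) at −0.21 and Grainyhead at 1.64 fell short of the threshold. Poly-T at 0.57 passed it. Without peaks beside a stronger peak, Stat92E at −0.41 passed it. In windows of 50 bp to each side, Twist at −0.50 and Su(H) at −0.34 fell short of the threshold. The TATA box at −0.56 passed it. In windows of 250 bp to each side, TAATTA at 0.0091, YAATTA at 0.16 and the TATA box at 0.24 reversed. TAATKG at −0.075, TTTATG at −0.16 and Mad/Brinker at 0.17 fell short of the threshold. CAGGTA at −0.31, Stat92E at −0.32 and poly-T at 0.46 passed it. With flanks at 500 bp, the CA repeat at 0.022 and Su(H) at −0.13 fell short of the threshold. The TATA box at −0.32 passed it. Against low-ranked regions, Pho at −0.41 reversed. The CA repeat at 0.35 fell short of the threshold. Stat92E at −0.45 passed it. Against windows matched on GC content and distance to a start, TAATTA at −0.18, YAATTA at −0.11 and Su(H) at −0.25 fell short of the threshold. Stat92E at −0.43 passed it. Against such windows, TAATTA at −0.17, YAATTA at −0.12, TAATKG at −0.16 and GAGA factor at 0.33 fell short among peaks overlapped by all 3 replicate lists. In the replicate 1 list TAATTA at −0.042, YAATTA at −0.054, TAATKG at −0.18 and GAGA factor at 0.26 fell short, as did TAATTA at −0.30 in the replicate 2 list. With 1 replicate left out, the ratios were −0.020 to 0.60 for TAATTA, 0.028 to 0.61 for YAATTA, −0.14 to 0.28 for TAATKG and −0.43 to 0.0037 for TTTATG. They were −0.67 to −0.32 for CAGGTA, −0.45 to 0.013 for the CA repeat, 0.14 to 0.47 for Mad/Brinker and −0.38 to −0.35 for Su(H). They were also −0.17 to 0.45 for the TATA box, 0.99 to 1.71 for Grainyhead and 0.33 to 0.79 for poly-T. Motifs called lower, 9 with the conservative list, were 5 with joint list B, in the replicate 1 list and with any 1 replicate left out, and 4 with joint list C, with all 3 replicates and at an IDR of 0.001.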

Other observations

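All tests in this part were chosen after the results were seen.

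Genes of several other families were examined. Mitochondrial ribosomal protein genes carried a peak more often than other genes, 23 of 73 (31.5% against 19.9%, adjusted exact p = 0.0431), led by mRpL4 (2L, 16329019 to 16329293, signal 714), mRpL41 (491) and mRpL17 (451). Peaks were scarcer at genes of the cuticle, of detoxification and of chemical senses. Of 70 cuticle protein genes only Cpr60D did (1.43%, adjusted exact p = 7.50e-05), of 85 cytochrome P450 genes 6 did (7.06%, adjusted exact p = 0.00928), of 51 odorant-binding protein genes 3 (5.88%, adjusted exact p = 0.0257) and of 60 gustatory receptor genes 4 (6.67%, adjusted exact p = 0.0257). Proteasome subunits (13 of 48, led by Rpn6), Mediator subunits (9 of 25, led by MED7), chaperonin subunits (4 of 8, led by CCT8) and translation initiation factors (12 of 44, led by eIF2Balpha) did not pass, with adjusted exact p of 0.311, 0.126, 0.111 and 0.339. Nor did TFIID subunits (3 of 15), complex I subunits (7 of 40) or aminoacyl-tRNA synthetases (6 of 33), each with an adjusted exact p of 1. These were Fisher's exact tests over 12 families. They were not repeated against matched gene sets or with a replicate left out, settings under which the olfactory receptor list lost its call.

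Peaks and DREF sites were also counted per gene. These are the same peaks as above, so the count is not separate evidence, and genes were not matched on number of starts. Of 1815 protein-coding genes with TATCGATA within 500 bp of a start, 872 carried a peak (48%), against 15.7% of the 12153 without one (log2 odds ratio 2.31, 95% interval 2.16 to 2.46, Fisher's exact p = 2.33e-189).

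Peaks in all 3 replicate lists and peaks missing from that of replicate 1 differed in sequence. The 892 peaks in all 3 replicate lists had a DREF site in 34.1% and a GAGA site in 11.1%, a mean GC content of 40.9% and a promoter share of 96.1%. The 255 peaks in the lists of replicates 2 and 3 but not replicate 1 had a DREF site in 5.88%, a GAGA site in 42.7%, a GC content of 50.1% and a promoter share of 78.8%. Between these classes the log2 odds ratio was 2.58 for GAGA (2.11 to 3.04, Fisher's exact p = 5.27e-27) and −3.01 for DREF (−3.77 to −2.24, p = 1.22e-22). The classes also differed in median signal, 293 against 167, and the DREF share differed with signal, at 5.02% in the lowest decile and 37.2% in the highest, so the difference was not separated from strength. Nor was it separated from the base composition of the replicate 1 list, which defines the classes.

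Patterning genes and ribosomal protein genes differed in overlap with the replicate 1 list. Of the 50 genes of 9 developmental lists combined that carried a conservative peak, such as C15, peb, Ubx and odd, the strongest peak overlapped the replicate 1 list for 13 (26.0%). For ribosomal protein genes it did for 28 of 29 (96.6%, Fisher's exact p = 2.10e-10), and for all protein-coding genes with a peak it did for 2010 of 2782 (72.3%). The median signal of these strongest peaks was 158 for the developmental and 286 for the ribosomal protein genes. Peaks of the same signal deciles overlapped the replicate 1 list in 50.2% and 84.3% of cases, so signal goes with part of the contrast, and the remainder was not tested.

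Among the 189 peaks more than 2000 bp from a start, GAGAGA was in 31.2% of windows against 7.75% of controls (log2 odds ratio 2.42). It was also higher at promoter peaks, in 17.4% against 7.04% (1.48), and the difference between these groups of peaks was not tested. Far from starts, CACACACA was in 12.2% against 4.81% (1.44) and TAATTA in 6.88% against 16.6% (−1.39, adjusted exact p = 0.00545). At promoter peaks neither passed, with CACACACA in 4.71% against 4.11% (0.21). TAATTA was there in 8.70% against 9.41% (−0.12, adjusted exact p = 0.548). All these controls lay 1000 bp away and were not matched on GC content. All 3 replicate lists overlapped 4.76% of these peaks, against 44.9% of promoter peaks, and 52.4% were in none. Their median signal was 109 against 189, and peaks of the same signal deciles as those far from starts were in all 3 lists in 14.5% of cases and in none in 40.9%, a difference that was not tested. The strongest with developmental genes beside them were in an intron of org-1 (signal 996), in the 5′ UTR of drm (2L, 3545375 to 3545527, signal 297), in an intron of Mef2 (2R, 9955102 to 9955517, signal 252) and in an intron of mam (2R, 14024604 to 14025019, signal 243). These were picked by their genes, and the start nearest the mam peak was that of CG18371. Other far peaks were stronger than the drm peak. Their nearest starts were those of Tim23 (572), CG16989 (546), CG15468 (426), inc (400) and CG11362 (329).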
